A study of Homo sapiens with 18 samples.

How the data were processed

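RNA from SW480 and HT29 cells was sequenced in 18 libraries that form 6 groups of 3. SW480 and HT29 are established human colorectal adenocarcinoma lines. The groups were SW480 and HT29 cells with an empty vector or with knockdown of LSD1, the histone demethylase encoded by KDM1A, and SW480 cells given DMSO or GSK-LSD1, an inhibitor of that enzyme. The knockdown reagent, the dose and the times are not given in the sources used here.

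Total RNA was extracted from scraped cells and made into libraries with a stranded mRNA kit, per the labels' protocols. The sample descriptions mark the knockdown libraries as stranded and the DMSO and GSK-LSD1 libraries as not stranded, although all carry the same kit. Whether counting used strand is not given in the sources used here, so genes that overlap another gene on the opposite strand are uncertain. The submitters' processing notes name FastQC 0.11.5, STAR 2.6.1a, SAMtools 1.9 and edgeR 3.24.0 and the human genome build hg38. The counting program and the gene annotation are not given in the sources used here.

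The authors deposited 3 tables of raw counts per gene symbol, 1 for each experiment, with 26485 genes each and 1 column per library. The values are whole numbers and the columns sum to totals between 31059334 and 73210197 counts, with 17408 to 19588 genes detected per library. In 28 entries a date stands in place of a gene symbol, and 2 of these dates occur more than once. These entries stayed in the fits under the date and none was named. No mitochondrially encoded gene was found in the tables, so that sign of RNA quality was not analysed here. The 4 ribosomal RNA genes took 0.214% to 0.270% of counts in the SW480 knockdown table, 1.37% to 2.34% in the HT29 table and 0.637% to 2.04% in the GSK-LSD1 table.

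Replicates were compared before they were averaged. The chi-square statistic per degree of freedom between replicates of a group ran from 4.55 to 183, so no pair of libraries agreed within sampling noise and each was kept as 1 replicate. Intervals and errors are those of 3 libraries per group.

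Each comparison was fitted in R 4.3.3 on the 6 libraries of its own table with edgeR 4.0.16. Low genes were removed with filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F test was run with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, with no minimum fold change. Standard errors of log2 fold changes were derived from the F statistic. Mean levels beside a fold change are CPM (counts scaled to a common library total, with TMM factors), with the SD over 3 libraries. The differences between the knockdown effects in both lines, and between the knockdown and GSK-LSD1 effects in SW480, were tested as interaction terms over 12 libraries. The tables come from separate experiments, so levels were set side by side across tables but not tested.

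In addition, 32 gene lists were drawn up for tests with limma 3.58.1. Of these, 30 were tested in each knockdown and 31 with GSK-LSD1, and the list of mitochondrially encoded genes in none. The camera test used log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, over lists with at least 5 tested members. It was repeated with the correlation estimated for each list. Genes named in the text were KDM1A, the 10 largest rises and falls among called genes with an average log2 CPM of at least 1 whose groups did not overlap, and genes of the PI3K and epithelial states (AKT1, AKT2, PIK3CA, CDH1 and VIM). Up to 3 called members of each list were added, chosen by the smallest p. For each difference of effects the 5 most positive and the 5 most negative called genes were named. Some genes chosen by this rule are not reported here and were not replaced. The designs, lists, naming rule and most alternatives were fixed before the data were examined. Coordinates are those of NCBI RefSeq on GRCh38.p14, an assembly in the same series as hg38.

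The replicate numbers in the labels recur in every group. In the GSK-LSD1 table, deviations of same-numbered libraries from their group means correlated at 0.31, 0.53 and 0.79 across genes, all above 0.1, so the numbers were taken to pair these libraries. The pairing comes from this check and not from a statement in the labels. A fit with the replicate number as a block is therefore given beside the GSK-LSD1 results where it changes a call. Not every library correlated best with its own number. Deviations from a group mean sum to 0, so a shift shared by the replicate 3 libraries alone would raise the other correlations too. The check therefore does not establish the pairing of replicates 1 and 2.

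The alternatives were DESeq2 1.42.0, RLE size factors, scaling by library size alone, no filter, a stricter filter of CPM above 1 in at least 3 libraries, and the older quasi-likelihood method. Also run were the replicate block, a test against a fold change of 1.5, all 18 libraries in 1 fit, and each library left out in turn. Chosen after the data had been seen were fits without ribosomal RNA, without the third GSK-LSD1 pair, and with a smooth trend of each library in transcript GC content and length removed. That correction used lengths and GC content from GENCODE 29 transcripts, which gave a value for 96.6% to 96.8% of tested genes.

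The count model was tested on simulated data with 200 changed genes drawn at the real means, library sizes and spread. The changed genes had an average log2 CPM of at least 1. Libraries were drawn independently, so shifts shared by libraries of both groups were left out. For a 1.5-fold change it recovered 85.3% of changed genes in the SW480 knockdown setting, 94.1% in the HT29 setting and 14.7% in the GSK-LSD1 setting. For a 2-fold change the shares were 97.0%, 100% and 55.2%. At 4-fold they were 100%, 100% and 98.5%. For the differences of effects the shares at a 2-fold change were 92.5% between the lines and 37.3% between knockdown and GSK-LSD1. The biological coefficient of variation was 10.1% in the SW480 knockdown table, 6.34% in the HT29 table and 20.5% in the GSK-LSD1 table.

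Words of 7 bases in 3' untranslated regions (UTRs) were related to fold changes in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The longest 3' UTR of each gene was taken from GENCODE 29. Log2 fold changes of genes with an average log2 CPM of at least 1 were rank-normalised, and quadratic terms in log2 UTR length and in UTR GC content were removed. Genes with and without each word were then compared, and KDM1A was left out.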

Results

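RNA abundance was measured in 18 libraries of colorectal cancer cells, 3 in each of 6 groups. The title of the series places the work in the relation between LSD1 and AKT activity in PIK3CA-mutant colorectal cancer. Totals ran from 37462496 to 38669866 counts in SW480 empty vector libraries and from 31059334 to 43204151 in SW480 knockdown libraries. They ran from 40802916 to 46073169 in HT29 empty vector, 37627162 to 42092531 in HT29 knockdown, 37130379 to 73210197 in SW480 DMSO and 33409837 to 47264811 in SW480 GSK-LSD1 libraries. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

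KDM1A, the gene that encodes LSD1, lies on chromosome 1 from 23019468 to 23083689 (GRCh38.p14). It had 5442, 5568 and 5969 counts in the SW480 empty vector libraries and 1120, 862 and 980 counts in the SW480 knockdown libraries. In HT29 it had 7932, 7911 and 7260 counts with empty vector and 795, 916 and 824 with knockdown. The SW480 level fell from 152 ± 8.90 to 26.1 ± 0.325 CPM (SD, n = 3), a log2 fold change of -2.55 (SE 0.08, edgeR adjusted p = 7.57e-08). The HT29 level fell from 178 ± 2.50 to 21.05 ± 2.06 CPM, a log2 fold change of -3.08 (SE 0.07, edgeR adjusted p = 1.66e-09). With DMSO it had 4925, 10883 and 6649 counts and with GSK-LSD1 5334, 3477 and 6038, a log2 fold change of -0.17 (SE 0.18, edgeR adjusted p = 1.00). GSK-LSD1 acts on the enzyme, so this last value checks no label.

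**Figure D1:**
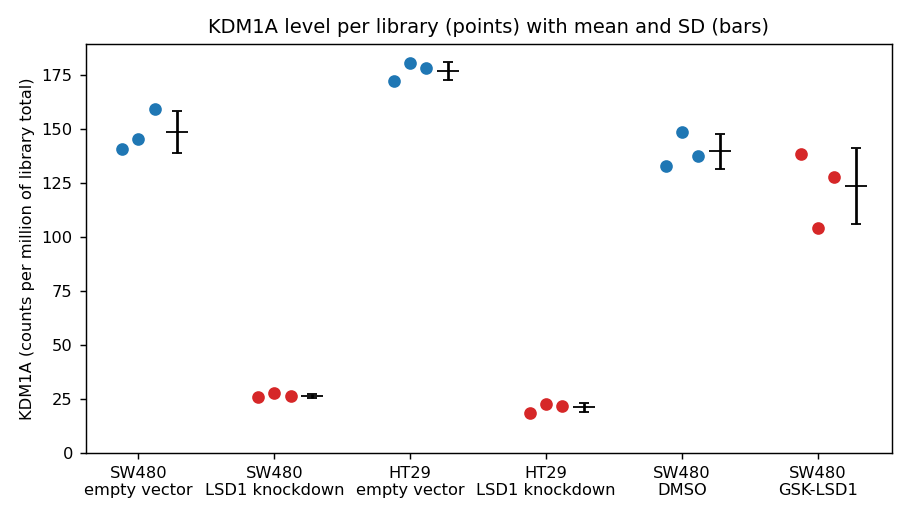
KDM1A in each library, in CPM of the library total, by group, with points for libraries and bars for the mean and SD of 3 libraries. Knockdown libraries sit between 18.9 and 27.8 CPM, below every empty vector, DMSO and GSK-LSD1 library, the lowest of which is at 104 CPM.

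In SW480 cells, part of the genes of sterol and fatty acid synthesis rose with LSD1 knockdown. INSIG1, a sterol-regulated brake on SREBP processing, rose from 19.0 ± 5.70 to 56.7 ± 7.34 CPM (log2 fold change 1.58, SE 0.18). HMGCS1, an enzyme early in cholesterol synthesis, rose by 1.02 (SE 0.12). Of 25 cholesterol synthesis genes tested, 12 rose and 0 fell, and 19 rose when adjusted over the list alone (camera adjusted p = 1.20e-07). The call was lost with an estimated correlation (adjusted p = 0.644). Of 20 fatty acid synthesis genes, 8 rose and 1 fell, and adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 9.70e-05, and adjusted p = 0.569 with an estimated correlation). Among them were MLXIPL at 1.29 (SE 0.15) and SREBF1 at 0.99 (SE 0.14), both transcription factors of lipid synthesis.

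Some genes of mesenchymal, epithelial, secretory and Wnt states also rose in SW480, and most members of these lists were not called. Of 22 mesenchymal genes 8 rose and 0 fell, with 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00658, and adjusted p = 0.644 with an estimated correlation). They included the actin-binding protein gene TAGLN (2.01, SE 0.38) and the matrix genes SPARC (0.90, SE 0.11) and TNC (0.89, SE 0.10). Of 30 epithelial junction and keratin genes 5 rose and 0 fell, 9 and 0 when adjusted over the list alone (camera adjusted p = 0.00506, and adjusted p = 0.644 with an estimated correlation), among them the junction genes CGN (0.85, SE 0.12) and CLDN1 (0.79, SE 0.13). CDH1, which encodes E-cadherin, rose from 7.26 ± 2.31 to 15.2 ± 4.93 CPM (1.07, SE 0.27, edgeR adjusted p = 0.0337), a call lost in DESeq2, without any 1 of the empty vector libraries and without knockdown replicate 1 or 2. VIM, which encodes the filament protein vimentin, stood at 1476 ± 56.7 and 1323 ± 82.3 CPM (-0.16, SE 0.08, edgeR adjusted p = 0.249). Of 9 goblet and secretory cell genes 3 rose and 0 fell, 4 and 0 when adjusted over the list alone (camera adjusted p = 0.00262, and adjusted p = 0.569 with an estimated correlation), with the mucin genes MUC13 at 1.41 (SE 0.31) and MUC1 at 1.21 (SE 0.22). Of 25 stem cell and Wnt target genes 6 rose and 0 fell, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00478, and adjusted p = 0.569 with an estimated correlation). NOTUM, APCDD1 and DKK1, which encode secreted or membrane inhibitors of Wnt signalling, rose by 1.12 (SE 0.14), 0.73 (SE 0.12) and 0.87 (SE 0.17). Of 5 enterocyte and colonocyte genes 1 rose and 0 fell, 2 and 0 when adjusted over the list alone (camera adjusted p = 0.0278, and adjusted p = 0.644 with an estimated correlation). Of 32 interferon-stimulated genes 5 rose and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.00867, and adjusted p = 0.644 with an estimated correlation). Of 4 fibroblast and endothelial markers measured, too few for a list test, 2 rose and 0 fell with the same counts when adjusted over the list alone, COL1A1 (1.13, SE 0.12) and PDGFRB (1.51, SE 0.26).

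In SW480 most heat shock genes measured were lower, as were some replication genes and few ribosome biogenesis and respiratory chain genes. Of 15 heat shock genes 8 fell and 0 rose, and 12 fell when adjusted over the list alone (camera adjusted p = 1.08e-06, and adjusted p = 0.569 with an estimated correlation). HSP90AA1, which encodes an abundant cytosolic chaperone, fell from 8333 ± 324 to 5938 ± 346 CPM (-0.49, SE 0.10). HSPA6 and its near-identical pseudogene HSPA7, whose reads could not be told apart here, had log2 fold changes of -1.18 (SE 0.27) and -1.23 (SE 0.26). Of 36 G1/S and replication genes 9 fell and 0 rose, and 18 fell when adjusted over the list alone (camera adjusted p = 5.41e-07, and adjusted p = 0.569 with an estimated correlation), with the cell cycle regulator E2F1 at -0.36 (SE 0.08). Of 33 MYC and ribosome biogenesis genes 4 fell and 0 rose, and 6 fell when adjusted over the list alone (camera adjusted p = 9.13e-06, and adjusted p = 0.569 with an estimated correlation). Of 34 nuclear oxidative phosphorylation genes 2 fell and 0 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.000207, and adjusted p = 0.644 with an estimated correlation). Other large falls were VAMP7, a vesicle fusion protein gene (-1.12, SE 0.08), the kinase-like gene STK40 (-1.09, SE 0.11), the receptor signalling gene EPS8 (-1.02, SE 0.11) and PRDX3, which encodes a mitochondrial peroxidase (-0.87, SE 0.08).

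Of the 39 PI3K-AKT-mTOR pathway genes tested in SW480, 3 rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.605). AKT1 fell from 235 ± 5.48 to 192 ± 12.8 CPM (-0.29, SE 0.08, edgeR adjusted p = 0.0372). PIK3CA stood at 24.2 ± 3.68 and 19.9 ± 2.33 CPM (-0.28, SE 0.13, edgeR adjusted p = 0.192). AKT2 had a log2 fold change of -0.03 (SE 0.07), was not called, and was at 0.04 when scaled by library size alone. The call of AKT1 was lost without any 1 of the empty vector libraries or without knockdown replicate 2 or 3.

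In all, 848 genes rose and 491 fell of 14515 tested in SW480, with 221 and 7 of them changed at least 2-fold. Rises were 63.3% of calls, against 83.2% (1307 and 264 genes) when scaled by library size alone, 52.5% (977 and 885) in DESeq2 and 52.3% (1060 and 965) after the GC content and length correction. In 4586 genes (31.6%) the 3 knockdown libraries all lay on the same side of the 3 controls, where chance gives 10%. The counts changed when 1 library was left out. Each such fit has fewer libraries, so a call can be lost for that reason and not because of the library left out. They were 278 and 112 without empty vector replicate 1, 348 and 100 without replicate 2, and 524 and 325 without replicate 3. They were 935 and 838 without knockdown replicate 1, 266 and 113 without replicate 2, and 703 and 248 without replicate 3. Of 85 named and called genes, 82 did not pass a test against a 1.5-fold change. Calls lost among the 85 were 43, 40 and 28 without empty vector replicates 1, 2 and 3 and 9, 45 and 24 without knockdown replicates 1, 2 and 3. Of the genes printed here, leaving out empty vector replicate 1 ended the calls of AKT1, CDH1, TAGLN, MUC13, IFI6, HSPA6, HSP90AA1, E2F1, BYSL, FOS and KDM5C. Leaving out replicate 2 ended those of AKT1, CDH1, MUC13, IFI6, BIRC3, HSPA6, HSPA7, HSP90AA1, BYSL, FOS and KDM5C. Replicate 3 did so for AKT1, CDH1, IFI6, E2F1 and KDM5C. Leaving out knockdown replicate 1 ended the calls of CDH1 and IFI6. Knockdown replicate 2 did so for AKT1, CDH1, TAGLN, MUC13, DKK1, IFI6, BIRC3, HSPA6, E2F1, BYSL, FOS and KDM5C. Knockdown replicate 3 did so for AKT1, BYSL, FOS and KDM5C. Scaling by library size alone ended the calls of AKT1, E2F1 and KDM5C, and the fit of all 18 libraries those of AKT1, E2F1, KDM5C, IFI6, BYSL, HSP90AA1 and EHMT1.

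In HT29 cells, most interferon-stimulated and antigen presentation genes tested rose with LSD1 knockdown. Of all genes tested in HT29, 53.1% were called in either direction, and list counts are to be read beside that share. IFI6, an interferon-induced mitochondrial protein gene, rose from 3.42 ± 0.205 to 32.9 ± 11.6 CPM (3.26, SE 0.25), and the antiviral genes OAS2 and MX2 rose by 3.04 (SE 0.26) and 3.02 (SE 0.32). Of 44 interferon-stimulated genes 41 rose and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 4.51e-13, and adjusted p = 0.483 with an estimated correlation). Of 24 antigen presentation genes 19 rose and 0 fell, 20 and 0 when adjusted over the list alone (camera adjusted p = 4.17e-05, and adjusted p = 0.443 with an estimated correlation). B2M, the shared light chain of class I molecules, rose from 633 ± 54.8 to 1269 ± 63.4 CPM. Of 22 NF-kB inflammatory genes 11 rose and 5 fell, 13 and 5 when adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.443 with an estimated correlation), with the chemokine gene CXCL8 at 1.89 (SE 0.10). Beside these groups, 4 of 5 leukocyte markers measured rose and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.00734, and adjusted p = 0.443 with an estimated correlation). LYZ, which encodes lysozyme, rose from 3620 ± 254 to 6726 ± 106 CPM, and ITGAM and CD14 rose from 4.76 ± 0.0746 to 13.8 ± 0.639 and from 1.88 ± 0.0196 to 4.57 ± 0.517 CPM.

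Part of the genes of differentiated colon and of mesenchymal cells rose in HT29. Of 21 enterocyte and colonocyte genes 11 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0169, and adjusted p = 0.578 with an estimated correlation). The adhesion molecule gene CEACAM6 rose from 41.9 ± 3.64 to 304 ± 42.2 CPM (2.86, SE 0.10), and CDH17, which encodes an intestinal cadherin, rose by 2.73 (SE 0.11). Of 33 epithelial junction and keratin genes 18 rose and 5 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.554 with an estimated correlation). CDH1 rose from 641 ± 6.59 to 707 ± 9.98 CPM (0.14, SE 0.05, edgeR adjusted p = 0.0482), a call lost on leaving out any 1 of the 6 libraries. Of 18 mesenchymal genes 9 rose and 1 fell, 9 and 2 when adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.443 with an estimated correlation). TNC rose by 2.24 (SE 0.18) and VIM by 3.06 (SE 0.23), the last from 0.248 ± 0.0441 to only 2.07 ± 0.319 CPM. Beside them, 2 of 4 fibroblast and endothelial markers, too few for a list test, rose and 0 fell, with the same counts when adjusted over the list alone: LUM (2.84, SE 0.10) and PECAM1 (1.79, SE 0.16). The largest rise was EMP3, a membrane protein gene, from 1.24 ± 0.225 to 17.9 ± 0.620 CPM of library total (3.82, SE 0.12), followed by the toll-like receptor gene TLR6 (3.63, SE 0.17) and TPRG1 (3.44, SE 0.18). CP, which encodes ceruloplasmin, rose by 3.15 (SE 0.10).

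Part of the lipid synthesis genes and most endoplasmic reticulum chaperone genes tested rose in HT29. Of 25 cholesterol synthesis genes 14 rose and 1 fell, and of 17 fatty acid synthesis genes 11 rose and 1 fell, with the same counts when adjusted over each list alone (camera adjusted p = 0.00682 and 0.00649, and adjusted p = 0.578 and 0.443 with an estimated correlation). INSIG1 rose by 0.99 (SE 0.07), while ACLY, which makes cytosolic acetyl-CoA, fell (-0.60, SE 0.05). Of 24 endoplasmic reticulum chaperone genes 19 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.000718, and adjusted p = 0.554 with an estimated correlation), with DNAJB9 at 1.08 (SE 0.09).

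Part of the genes of the PI3K pathway, of FOXO output and of amino acid stress fell in HT29. Of 38 PI3K-AKT-mTOR pathway genes 21 fell and 6 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00649, and adjusted p = 0.443 with an estimated correlation). PIK3CA, the catalytic subunit gene named in the title, fell from 30.04 ± 0.930 to 19.4 ± 0.908 CPM (-0.63, SE 0.06, edgeR adjusted p = 1.71e-05). AKT1 fell from 127 ± 6.26 to 95.2 ± 8.35 CPM (-0.41, SE 0.07, edgeR adjusted p = 0.000509), and AKT2 was not called (-0.13, SE 0.06, edgeR adjusted p = 0.0848). DEPTOR, which encodes an inhibitor of mTOR, fell (-1.04, SE 0.11). Of 21 FOXO target genes 10 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0307, and adjusted p = 0.443 with an estimated correlation), and PDK4 was at -1.51 (SE 0.10). Of 29 integrated stress response genes 18 fell and 0 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.000301, and adjusted p = 0.443 with an estimated correlation), with the serine synthesis enzyme gene PSAT1 at -0.72 (SE 0.06). Of 19 LSD1 and CoREST complex genes, KDM1A included, 11 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0169, and adjusted p = 0.443 with an estimated correlation). The fall of KDM1A was set by the knockdown, and the list was not tested without it.

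Part of the proliferation, respiratory and chromatin genes also fell in HT29, where 3774 of all 14256 genes tested fell. Of 36 G1/S and replication genes 23 fell and 0 rose, with the same counts when adjusted over the list alone (camera adjusted p = 4.17e-05, and adjusted p = 0.578 with an estimated correlation). CCNE1, which encodes cyclin E1, was at -0.55 (SE 0.07). Of 38 G2/M genes 12 fell and 4 rose, 11 and 3 when adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.869 with an estimated correlation). Of 33 MYC and ribosome biogenesis genes 17 fell and 0 rose (camera adjusted p = 0.00125, and adjusted p = 0.554 with an estimated correlation). Of 34 nuclear oxidative phosphorylation genes 17 fell and 5 rose (camera adjusted p = 0.0226, and adjusted p = 0.856 with an estimated correlation). Of 26 DNA methylation and Polycomb genes 13 fell and 0 rose (camera adjusted p = 0.0211, and adjusted p = 0.554 with an estimated correlation), among them the histone methyltransferase gene EHMT1 (-0.55, SE 0.05). For these 3 lists the counts were the same when adjusted over the list alone. The largest falls after KDM1A were HEPACAM2 (-2.17, SE 0.19) and the small GTPase gene MRAS (-1.94, SE 0.13). The trypsinogen genes PRSS1 (-1.76, SE 0.23) and PRSS2 (-1.68, SE 0.16) are close paralogs and could not be told apart with certainty.

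In all, 3803 genes rose and 3774 fell of 14256 tested in HT29, with 651 and 127 of them changed at least 2-fold. In 8620 genes (60.5%) the groups did not overlap, where chance gives 10%. A fit of all 18 libraries called 1931 and 987 genes, and a test against a 1.5-fold change called 651 and 109. The fit of all 18 libraries ended the calls of AKT1, CDH1, BYSL and KDM5C, and that without a filter the call of CDH1.

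**Figure D2:**
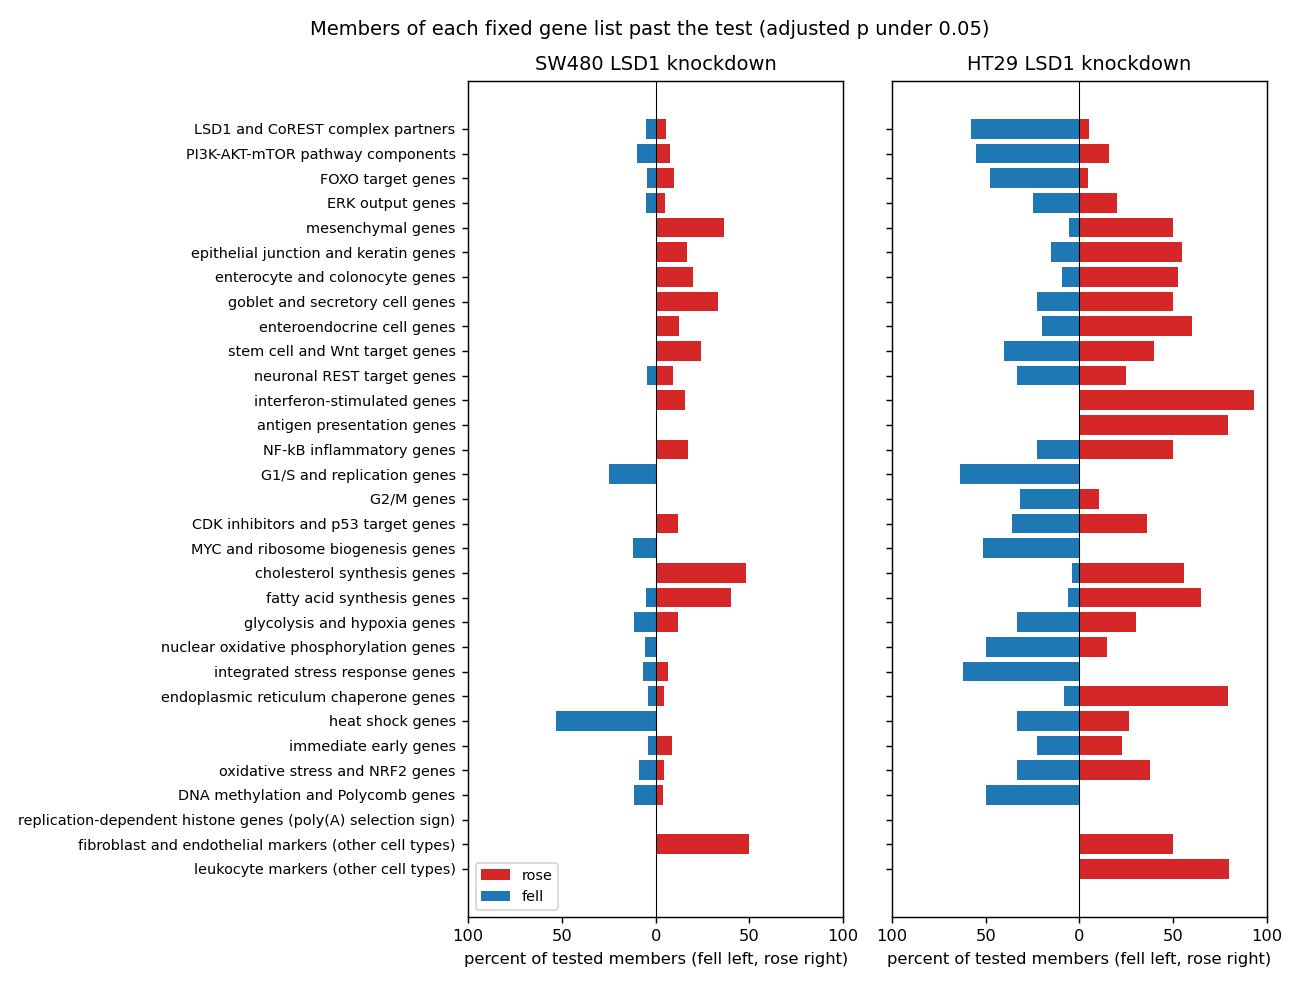
Percent of tested members of each fixed gene list that rose (red, to the right) or fell (blue, to the left) at an edgeR adjusted p under 0.05, for the SW480 knockdown (left panel) and the HT29 knockdown (right panel). In HT29, 41 of 44 interferon-stimulated genes rose, and in SW480, 12 of 25 cholesterol synthesis genes did.

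Of the lists tested with camera, 12 of 30 were called in the SW480 knockdown and 19 of 30 in the HT29 knockdown, and with an estimated correlation 0 were in either. The LSD1 and CoREST list includes KDM1A, the knockdown target, in every count. The remaining lists were not called. In SW480 these were LSD1 and CoREST partners (1 rose, 1 fell), FOXO targets (2, 1), ERK output (1, 1), enteroendocrine (1, 0) and neuronal REST target genes (2, 1), antigen presentation (0, 0), NF-kB (4, 0), G2/M (0, 0), CDK inhibitors and p53 targets (3, 0), glycolysis and hypoxia (4, 4), integrated stress response (2, 2), endoplasmic reticulum chaperones (1, 1), immediate early (2, 1), NRF2 (1, 2), DNA methylation and Polycomb (1, 3), replication-dependent histones (0, 0) and leukocyte markers (0, 0). Adjusted over the list alone, the counts became 6 and 2 for FOXO targets, 7 and 2 for NF-kB, 3 and 1 for p53 targets, 4 and 9 for glycolysis and hypoxia, 3 and 4 for the integrated stress response, 3 and 2 for immediate early, 2 and 6 for NRF2, 1 and 4 for Polycomb genes and 1 and 0 for leukocyte markers, and were the same for the others. In HT29 they were ERK output (4 rose, 5 fell), goblet (11, 5), enteroendocrine (3, 1), stem cell and Wnt target (10, 10) and neuronal REST target genes (3, 4), CDK inhibitors and p53 targets (9, 9), glycolysis and hypoxia (10, 11), heat shock (4, 5), immediate early (5, 5), NRF2 (9, 8) and replication-dependent histones (0, 0). Adjusted over the list alone, they became 5 and 6 for ERK output, 12 and 11 for glycolysis and hypoxia, 4 and 6 for heat shock and 9 and 9 for NRF2 genes, and were the same for the others.

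Both knockdowns moved many genes the same way. Of 12994 genes tested in both lines, 427 rose in both, where independent lists of these sizes would share 167, and 383 fell in both, where they would share 135. Another 48 rose in SW480 and fell in HT29, and 12 did the reverse. Of 1150 genes called in SW480, 999 (86.9%) had the same sign in HT29. Log2 fold changes correlated across genes with Pearson's r of 0.481 and Spearman's rho of 0.516. Genes are not independent replicates, so no p is given. The comparisons share no libraries. INSIG1, TNC, SAMD9, BIRC3 and ABCC3 were among the named genes that rose in both, and AKT1, EHMT1, KDM5C, GCLM, BYSL and FOS were among those that fell in both. BIRC3 in SW480 LSD1 knockdown against empty vector was no longer called after the GC content and length correction, where its value went from 0.75 (SE 0.17) to 0.67 (SE 0.21). The 810 shared calls of the SW480 and HT29 knockdowns became 235 without SW480 empty vector replicate 1, 253 without replicate 2, 238 without SW480 knockdown replicate 2 and 537 without knockdown replicate 3.

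**Figure D3:**
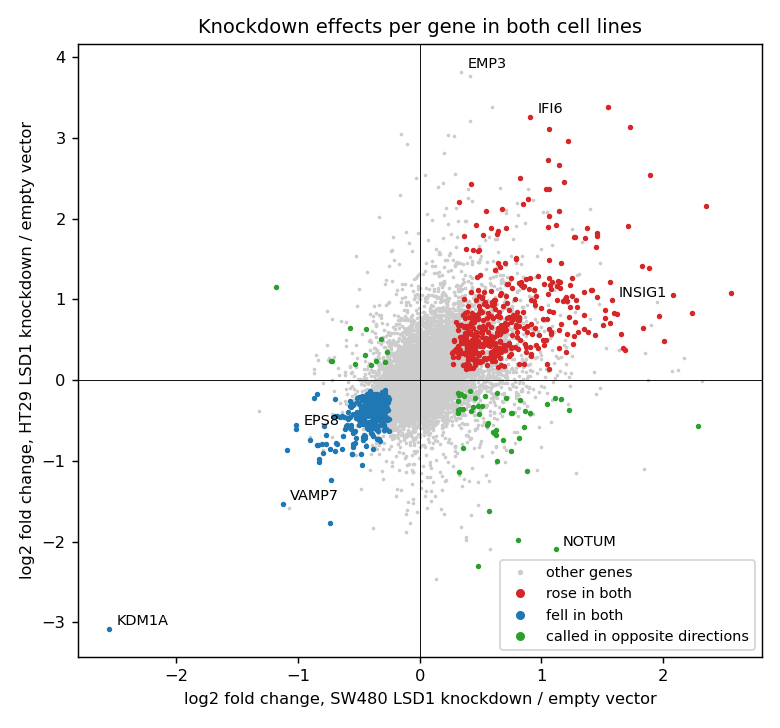
Log2 fold change of each gene with LSD1 knockdown in SW480 (horizontal axis) and HT29 (vertical axis), with 1 point per gene tested in both lines. Red points mark 427 genes that rose in both, blue points 383 that fell in both, and green points genes called in opposite directions.

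Among the lists tested, interferon-stimulated genes had the largest median difference between the lines, with the higher effect in HT29. Of 44, 16 had a negative difference, SW480 minus HT29, and 0 a positive one (median -0.76, camera adjusted p = 2.41e-14, and adjusted p = 0.435 with an estimated correlation). Of 23 mesenchymal genes 5 had a negative and 3 a positive difference, and the list was not called (camera adjusted p = 0.461). The difference was -3.52 (SE 0.19) for EMP3, -3.25 (SE 0.22) for VIM, -3.06 (SE 0.32) for the matrix gene CTHRC1, -2.85 (SE 0.32) for OAS2 and -2.78 (SE 0.36) for MX2. Each of these genes started higher in SW480 than in HT29 empty vector libraries. OAS2 stood at 24.5 ± 3.81 and 3.23 ± 0.431 CPM of library total, and MX2 at 5.07 ± 0.222 and 0.572 ± 0.0692. In HT29 knockdown libraries they reached 26.9 ± 9.84 and 4.76 ± 1.82 CPM. On the other side, NOTUM rose from 29.9 ± 5.04 to 68.3 ± 10.5 CPM of library total in SW480, fell from 0.891 ± 0.0805 to 0.205 ± 0.158 CPM in HT29, and differed by 3.18 (SE 0.45). The kinase gene SPEG differed by 2.76 (SE 0.31), the goblet cell mucin gene MUC2 by 2.91 (SE 0.84), the lipid droplet gene PLIN4 by 2.83 (SE 0.69) and MSX1 by 4.09 (SE 0.86). MSX1 had 5 to 13 counts in HT29 empty vector and 0 to 1 in HT29 knockdown libraries, VIM 9 to 12 and CTHRC1 4 to 10 in HT29 empty vector, and in SW480 empty vector libraries PLIN4 had 3 to 5 and MUC2 6 to 18 counts, so these differences rest on few reads. MUC2 had 10 to 88 counts in SW480 knockdown libraries, and without knockdown replicate 2 the value for MUC2 in difference between the knockdown effects in SW480 and HT29 was 1.02. The call of MUC2 was also lost without SW480 empty vector replicate 1 or 2 or any HT29 library and in DESeq2, and that of PLIN4 without SW480 empty vector replicate 1 or SW480 knockdown replicate 2.

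Of 15836 genes tested, 497 had a positive and 814 a negative difference between the lines by edgeR. Positive differences were 37.9% of calls, against 62.5% (913 and 547 genes) when scaled by library size alone. The counts moved by over 1.5 times without HT29 empty vector replicate 2 (311 and 476) or replicate 3 (303 and 503) and without HT29 knockdown replicate 3 (300 and 551).

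In SW480 cells given GSK-LSD1, no gene was called against DMSO. Of 14885 genes tested, 0 rose and 0 fell by edgeR, with 278 at an unadjusted p under 0.05, and DESeq2 called 0, with 228 at an unadjusted p under 0.05. The 3 GSK-LSD1 libraries lay on the same side of the 3 DMSO libraries in 1008 genes (6.77%), where chance gives 10%. The share at an unadjusted p under 0.05 was also below the 0.05 that chance gives. With the replicate block 1719 genes had an unadjusted edgeR p under 0.05. The 0 calls of the fit without the block are therefore no evidence of no effect. AKT1 stood at 304 ± 65.3 CPM with DMSO and 319 ± 86.9 with GSK-LSD1 (0.07, SE 0.24), and PIK3CA at 25.0 ± 3.91 and 19.5 ± 4.47 (-0.36, SE 0.21). AKT2 and VIM had log2 fold changes of 0.12 (SE 0.19) and -0.01 (SE 0.24). CDH1 was at 0.500 ± 0.120 and 0.197 ± 0.0469 CPM, from 6 to 46 counts per library. In simulated data at this spread 14.7% of 1.5-fold and 55.2% of 2-fold changes were recovered, so changes of that size may have been missed. The simulation held no shift shared by libraries of both groups and no changed gene of low level. Its shares may therefore not hold for the real libraries or for low genes.

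With the replicate pairs as a block, 12 genes rose with GSK-LSD1 and 0 fell. They were RAC2 (1.11, SE 0.19), GPER1 (1.03, SE 0.16), KISS1R (1.00, SE 0.14), ESM1 (0.97, SE 0.16), CLDN3 (0.88, SE 0.13), RASGEF1C, ROBO3, ENTPD8, NOXA1, MTRNR2L2, FBLIM1 and TMEM173 (0.65, SE 0.11), chosen after their values were seen. TMEM173, which encodes the DNA-sensing adaptor STING, also rose in the SW480 (1.08, SE 0.10) and HT29 (1.13, SE 0.10) knockdowns. KISS1R (1.01, SE 0.24), ENTPD8 (1.08, SE 0.21) and NOXA1 (0.83, SE 0.19) rose in the SW480 knockdown too, and the other 8 were not called there. These knockdown values are from the fit without the block. With the knockdown fit blocked as well, 10 of the 12 were called higher in SW480, where independent lists would share 2.10. In the HT29 knockdown, also without the block, ROBO3 (0.90, SE 0.20), FBLIM1 (0.55, SE 0.09), MTRNR2L2 (0.52, SE 0.12) and CLDN3 (0.29, SE 0.08) rose, and GPER1 fell (-1.02, SE 0.21). KISS1R, ESM1 and RASGEF1C were not tested in HT29.

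Of 31 lists tested with GSK-LSD1, 4 were called by camera, and 0 genes of these lists were called over all genes or when adjusted over the list alone. Nuclear oxidative phosphorylation genes were higher, with a median log2 fold change of 0.14 and 29 of 34 members above 0. DNA methylation and Polycomb, PI3K-AKT-mTOR and fatty acid synthesis genes were lower, with medians of -0.10, -0.06 and -0.09. All 4 had a camera adjusted p of 0.0366, and adjusted p = 0.726 with an estimated correlation. With the replicate block 0 lists were called (adjusted p of 0.0733 for the Polycomb list and 0.0745 for the others). Without DMSO replicate 3 or GSK-LSD1 replicate 1, 0 lists were called, 1 without GSK-LSD1 replicate 2 and 7 without GSK-LSD1 replicate 3. The replication-dependent histone genes, a sign of poly(A) selection, were not called, with 15 of 20 members higher and 5 lower (median 0.17, camera adjusted p = 0.151).

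Between the knockdown and GSK-LSD1 in SW480, 1 of 15251 genes differed by edgeR, KDM1A itself (-2.39, SE 0.20, adjusted p = 0.000202), with 1276 genes at an unadjusted p under 0.05. DESeq2 called 40 positive and 30 negative differences. The fit with the replicate block called 696 and 482, and the fit without the third GSK-LSD1 pair 44 and 25. Leaving out GSK-LSD1 replicate 3 alone gave 6 and 2, and leaving out SW480 empty vector replicate 2 or DMSO replicate 2 gave 1 and 1. Log2 fold changes of the knockdown and of GSK-LSD1 correlated across 14123 genes with Pearson's r of 0.120 and Spearman's rho of 0.0124. Genes are not independent replicates here either.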

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

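The test of an expressed hairpin, the GC content and length correction and the count of splits that kept a real grouping were chosen after the results were seen, and the other tests in this part were planned before.

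Interferon-stimulated genes stood out between the lines, with a median difference of effects, SW480 minus HT29, of -0.76, a negative difference called for 16 of 44 members, and the list call lost with an estimated correlation (adjusted p = 0.435). Within HT29, 41 of 44 were called higher with knockdown. A trend with GC content and length argues poorly for this, since 41 of the 41 called genes (100%) stayed called once it was removed. A single HT29 library does too, since at least 38 of the 41 (92.7%) stayed called without any 1 library. A response to any expressed hairpin cannot be told apart from an effect of LSD1 loss, because the tables hold no control hairpin, and the smaller SW480 change (-0.76 relative to HT29) may reflect the line as well as the reagent, so that LSD1 loss raises these genes stays a hypothesis.

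The genes below differed by a test of the difference between the lines. MSX1 (4.09), NOTUM (3.18), MUC2 (2.91), PLIN4 (2.83) and SPEG (2.76) had the more positive effect in SW480, and MSX1, VIM and CTHRC1 were near the detection floor in HT29 empty vector. EMP3 (-3.52), VIM (-3.25), CTHRC1 (-3.06), OAS2 (-2.85) and MX2 (-2.78) had the more positive effect in HT29. Each of them started from a higher level in SW480 than in HT29 empty vector libraries. Whether the unequal starting level accounts for the difference was not tested. In 1 of 40 drawn splits within each experiment, the real one, as many genes differed, with 1311 genes against at most 923 in another. The 4 other splits with the most calls, 574 to 923, all kept the real HT29 grouping, and every split that kept neither grouping called 0, so this count says nothing about chance.

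Lists that differed between the lines by camera, as median differences of SW480 minus HT29, were the LSD1 and CoREST partners with KDM1A included (0.046), PI3K-AKT-mTOR components (0.13), FOXO targets (0.26), stem cell and Wnt targets (0.18), G2/M genes (0.11), cholesterol synthesis (0.12) and integrated stress response genes (0.26). Antigen presentation genes (-0.38), endoplasmic reticulum chaperones (-0.34) and heat shock genes (-0.29) differed the other way. With an estimated correlation the smallest adjusted p for a list difference between the lines was 0.155, for FOXO targets.

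Between the knockdown and GSK-LSD1 in SW480, KDM1A differed by -2.39. By camera, mesenchymal (0.37), epithelial junction (0.34), enterocyte (0.62), goblet (0.70), interferon-stimulated (0.20), NF-kB (0.17), cholesterol synthesis (0.32) and fatty acid synthesis genes (0.36) had the more positive effect with the knockdown. G1/S (-0.14), oxidative phosphorylation (-0.27), heat shock (-0.25) and replication-dependent histone genes (-0.35) had the more negative one. With an estimated correlation the smallest adjusted p among these was 0.0889, for fatty acid synthesis. Of 40 drawn splits, 7, the real one included, gave as many genes as the real 1, so by the bound set before chance was not excluded. Of the 6 others 5 kept the real knockdown grouping, and with it the change of KDM1A, with up to 1191 genes. These 5 do not stand for chance, so the share cannot tell chance from a real difference. The remaining 1 kept neither grouping and called 1233, the highest, and the reason was not tested.

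In the single comparisons 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split gave 1339 called genes in the SW480 knockdown and 7577 in the HT29 knockdown, each in 1 of 10 splits, with 0 as the highest other in both. With GSK-LSD1 it gave 0, as did all 10 splits, with 0 as the highest other. For gene lists the real split gave 12 in SW480, and 3 of 10 splits gave as many, with 18 in another. It gave 19 in HT29, in 1 of 10 splits, with 12 as the highest other, and 4 with GSK-LSD1, where 4 of 10 splits gave as many and another gave 9. The list calls in SW480 and with GSK-LSD1 were therefore matched by other groupings of the same libraries. Those groupings still part the conditions unevenly, so they are not free of the real contrast. With the GSK-LSD1 pairs as a block, 4 splits part the 3 pairs, and the real one gave 12 genes, in 1 of 4, with 0 as the highest other.

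The 810 calls shared by both knockdowns were reached in 1 of 100 pairs of splits, the real one, with 0 in the highest other. Every other split of either table called 0 genes, so no other pair could share any, and this count says nothing about chance.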

How the results depend on the processing

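The fits without ribosomal RNA, with GC content and length correction, and without the third GSK-LSD1 pair were chosen after the results were seen. KDM1A kept its direction in every alternative and its call in both knockdowns, with ranges on leaving out 1 library of -2.58 to -2.50 for KDM1A in SW480 LSD1 knockdown against empty vector and -0.29 to -0.01 for KDM1A in SW480 GSK-LSD1 against DMSO. Of the comparisons of single genes, 3244 kept direction and side of the threshold, 419 lost a call, 4 gained one and 10 changed sign, none of them called. For list directions 260 were the same and 94 lost the call, and for counts 184 stayed within 1.5 times and 71 did not. The cause was not tested, except that a fold minimum leaves fewer calls by construction. Leaving out 1 library could raise the counts as well as lower them. Without SW480 knockdown replicate 1 they were 935 higher and 838 lower.

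In the SW480 knockdown (848 higher, 491 lower), DESeq2 gave 885 lower, library size alone 1307 and 264, all 18 libraries 514 and 185, the 1.5-fold test 5 and 2, and GC correction 965 lower. Leaving out 1 library gave 266 to 935 higher and 100 to 838 lower. In HT29 (3803, 3774) the 1.5-fold test gave 651 and 109 and all 18 libraries 1931 and 987, and leaving out 1 library gave 3180 to 3967 and 2931 to 3938. With GSK-LSD1, GC correction with the replicate block gave 10 higher, leaving out the third pair 2, and 20 with the block, and leaving out 1 library 0. Differences between the lines (497 positive, 814 negative) became 834 positive in DESeq2, 913 with library size alone, 34 and 72 in the 1.5-fold test, 110 and 202 with all 18 libraries, and 300 to 545 and 476 to 896 without 1 library. Differences between knockdown and GSK-LSD1 (0, 1) became 40 and 30 in DESeq2, 19 and 10 with all 18 libraries, 44 and 25 without the third pair, and 0 to 6 and 1 to 2 without 1 library. The 810 shared calls of the SW480 and HT29 knockdowns became 52 at an absolute log2 fold change of at least 1 and 235 to 1128 without 1 library.

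List calls (12, 19 and 4) became 0, 0 and 0 with an estimated correlation. With fry, which asks only whether a list's own genes move, they were 3 in SW480 and 0 with GSK-LSD1, and with library size alone 0 with GSK-LSD1. Leaving out 1 library gave 8 to 15, 14 to 19 and 0 to 7.

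The replicate numbers were not taken to pair the knockdown libraries, because not all correlations were above 0.1. They were 0.49, 0.08 and 0.48 in SW480 and 0.14, 0.24 and -0.09 in HT29. In SW480 only replicate 2 fell short, so a pairing that the main fit leaves out is not excluded there. In no table did every library correlate best with its own number. The replicate block moved the SW480 counts to 2562 and 1991, the differences between lines to 1140 and 1536, those between knockdown and GSK-LSD1 to 696 and 482, and shared knockdown calls to 2659. With GSK-LSD1, where the numbers were taken to pair the libraries, the block gave 12 higher and 0 lists. With the knockdown fits blocked too, 10 calls were shared with the SW480 knockdown, where independent lists would share 2.10. With the HT29 knockdown 5 were shared, where independent lists would share 2.45. Only 9 of the 12 were tested in HT29, and 1 of them was called lower there. The block changed no other call with GSK-LSD1.

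Signs changed for genes near 0. AKT2 in SW480 LSD1 knockdown against empty vector was 0.042 with library size alone. VIM in SW480 GSK-LSD1 against DMSO was 0.0019 in DESeq2, 0.0019 with RLE, 0.014 with all 18 libraries and 0.0066 without ribosomal RNA. Without 1 library AKT1 in SW480 GSK-LSD1 against DMSO ranged from -0.18 to 0.25, AKT2 in SW480 GSK-LSD1 against DMSO from -0.052 to 0.25 and VIM from -0.20 to 0.18.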

Other observations

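Chosen after the results were seen were the comparison of levels between tables, the search for the joined word in KDM1A transcripts, the PIK3CA test, the GC content and length correction and the fits without the third GSK-LSD1 pair.

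Levels of some epithelial genes were set side by side in the SW480 control libraries of both experiments. CDH1 stood at 7.06 ± 2.20 CPM of library total with empty vector and 0.500 ± 0.126 with DMSO, and MUC13 at 1.17 ± 0.208 and 0.0250 ± 0.00374 CPM. LCN2 stood at 14.97 ± 3.78 and 3.10 ± 0.195 CPM, CLDN4 at 37.6 ± 6.69 and 23.4 ± 1.71 CPM and MUC1 at 1.35 ± 0.307 and 1.38 ± 0.183 CPM. VIM stood at 1438 ± 65.7 and 1516 ± 60.6 CPM and ZEB1 at 32.2 ± 5.88 and 32.9 ± 5.66 CPM. The tables come from separate experiments with library types described differently, and these levels were not tested against each other.

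Genes that fell in both knockdowns shared short words in their 3' UTRs. Of all words of 7 bases, AACTGAA was the most strongly tied to lower fold changes in SW480 (z = -8.63) and also ranked 1 in HT29 (z = -7.58), but 427 with GSK-LSD1 (z = -2.15). It was present in 118 of 370 genes that fell in both (31.9%), against 19.9% of other genes, a ratio of 1.60, and in 13.6% of genes that rose in both. The word was picked for its tie to falls in SW480 and these shares take no account of UTR length or GC content, so the ratio in part restates that choice, while the rank in HT29 does not. With length and GC content of the UTR held fixed, genes with AACTGAA differed from genes without it by a log2 fold change of -0.06 in SW480 (-8.64 standard errors), -0.07 in HT29 (-6.49) and -0.01 with GSK-LSD1 (-2.30). These pooled shifts are small, and the ranks were predicted before they were computed, although the idea came from seeing which genes fell.

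The words overlap and join to TTAAACTGAA, which occurs in 3 of 3 annotated KDM1A transcripts, outside the 3' UTR, and in transcripts of 163 of 19444 genes (0.838%). A candidate explanation is a seed match of the kind a small hairpin RNA gives, with 1 reagent in both lines. The search in KDM1A was made once the words were known and its outcome was anticipated from general knowledge of KDM1A hairpins, so it is no blind test, and the reagent's sequence is not given in the sources used here. Among genes with none of the joined words, 162 fell in both where independent lists would share 66.4, a ratio of 2.44, and among genes with any of them 208 did against 85.6, a ratio of 2.43. The expected number rests on each group's own falls, which such a match would itself raise. Equal ratios therefore cannot tell whether the words add shared falls. By plain counts, 208 of 4267 genes with any of the words fell in both, and 162 of 5811 with none. These counts do not hold UTR length fixed. An excess was thus also seen among genes with none of the 4 joined words in the longest 3' UTR. Matches to other words, matches outside that UTR and indirect effects were not separated from this group. How much of the shared falls such a match accounts for therefore stays open. A trend with GC content and length is argued against, since 374 of the 383 shared falls (97.7%) stayed called and lower in both after its removal.

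PIK3CA, lower in HT29 and central to the question of the study, has a 3' UTR of 5729 bases with 8 of the joined words. The first comparison, with 805 genes matched on UTR length alone, found as many words in 40 (4.97%), just under the bound of 5% set for calling it unusual. Matching on GC content as well was added after that value was seen, and 22 of 251 genes (8.76%) then had as many, which lies between the bounds. Whether a seed match may have lowered PIK3CA therefore stays open. AKT1, EHMT1, STK40, LYPD1, HEPACAM2, MRAS, RASL10B and TNFAIP8L3, which also fell in at least 1 line, have 0 of these words, and VAMP7 has 2, as many as 34.4% of matched genes. The call of LYPD1 in SW480 was lost without any 1 of the empty vector libraries or without knockdown replicate 2 or 3. EPS8, among the larger falls in SW480, has 7, as many as 4 of 478 genes matched on length and GC content (0.837%), and PRDX3 has 4 (1.83% of matched genes).

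The spread of the third pair of GSK-LSD1 libraries was weighed as the reason for 0 calls. Without that pair 2 genes were called, and 20 with the replicate block, at the bound that had been set, so this may account for part of the result but cannot be told apart from a small effect with so few pairs. Among the 20 were RPPH1 (1.64), TERC (1.54), BCYRN1 (1.05) and HIST1H2AE (1.62), whose RNAs mostly lack poly(A) tails, beside KISS1R (1.14), IFI6 (1.02), CLDN3 (0.93) and APOE (0.93).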
